A study of Homo sapiens with 4 samples.

How the data were processed

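Gene expression was measured in FaDu cells, an established line of squamous carcinoma of the hypopharynx, on 4 Agilent microarrays with a single dye (Cy3). Per the labels, the parental cells received 0 Gy, and populations that regrew between repeated X-ray exposures were collected after totals of 20, 40 and 60 Gy. Each dose was measured on 1 array, so the comparisons of 2 arrays have no replicate check. The 4 arrays share 1 slide and 1 scan time per the file headers, so neither could be fitted as a block. Array position and dose cannot be told apart.

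Per the file headers, the authors' scanner images were quantified with Agilent Feature Extraction 11.5.1.1 under protocol GE1_1105_Oct12, while the submitters' processing notes name version 10.7. The deposited scanner values are spot intensities on a linear scale. The processed signal is the intensity after the software's background subtraction, per the file headers, and it carries no normalisation between arrays. The deposited flags mark spots that are outliers, saturated or well above background. Each array holds 180880 spots, of which 4974 are controls. No spot was marked saturated. The deposited value table of the series holds 65522 probes as linear intensities, 65454 of them among the 75149 non-control probes of the array. In 100% of its cells that have a value in both sources, it equals the geometric mean of the probe's spots not marked as outliers, within 1e-04 on the log2 scale. Its scale is therefore linear, its columns are not centred on one another, and a higher value is a brighter spot. Its column medians are 23.3 at 0 Gy, 30.4 at 20 Gy, 74.8 at 40 Gy and 40.9 at 60 Gy. It was used as an alternative source.

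Spots marked as non-uniform or population outliers were left out, and the remaining spots of a probe were averaged as log2 processed signal. Of the 75149 non-control probes, 49541 are printed in 2 spots and 25608 in 3 spots. After this step 134, 71, 198 and 109 probes had no value at 0, 20, 40 and 60 Gy. Each array's 75th percentile over all non-control probes was then subtracted, since over 50% of the probes were above background on every array. A probe counted as above background where more than 50% of its spots were marked so. A pair of arrays was compared at a probe above background on at least 1 of them. Where it was above background on 1 side, the difference is a lower bound, taken against the higher of the dim probe's own signal and the lowest signal of a probe above background on that array. A probe was counted at a difference of 2-fold or more (1 on the log2 scale).

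Differences between 2 arrays are values with no test. Technical error comes from the repeated spots of a probe on 1 array and measures neither culture nor labelling. Both models with residual degrees of freedom were fitted across probes with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, Benjamini-Hochberg adjustment, threshold 0.05). The first compared the 3 irradiated arrays with the parental array and the second fitted a straight line in dose. Both have 2 residual degrees of freedom. In the first model these come only from differences between the irradiated arrays, so differences between doses are taken as noise. The lone parental array is assumed to vary like the others, and the irradiated populations may share ancestry, so the p-values measure only the spread between these arrays. Tables were read with the R package data.table, version 1.17.8, and figures were drawn with matplotlib 3.10.9.

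The scanner files give probe identifiers without gene symbols, and the reference tables used here do not list those identifiers. The 33 gene lists fixed before the data were examined, the rule for several probes of a gene, the count over long non-coding RNAs and most of the rule for named genes therefore could not be applied. That rule took, among probes above background on all 4 arrays, those with the largest smallest absolute difference over the 3 doses in 1 direction, together with the leading probes of each dose, step, list and model. Only 2 probes higher and 2 lower by its first part are named, by identifier. The control probes for GAPDH and PGK1 carry gene names. In place of the lists, probes were grouped after the data were seen by the RNA class written in the probe name (tRNA, snRNA, snoRNA_scaRNA, rRNA, imsncRNA, RNS and others). The names imsncRNA, RNS and the plain p-numbers are used as the file gives them, with no meaning assumed. A class median was set against 10000 random lists (500 for Agilent catalogue probes and for p-number probes with and without a version) of the same size drawn from the other probes within 20 bins of mean signal. The percentile describes these arrays and is not a p-value.

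On simulated arrays of 40495 probes with a noise SD of 0.2, varied between probes, the count over all 3 doses recovered 85.5% of probes changed by 1.5 on the log2 scale and 100% of those changed by 2. The order by dose recovered 75.4% and 90.3%, limma's comparison with the parental array 72.5% and 98.4%, and limma's dose trend 47.8% and 85.5%. Among the 40295 unchanged probes the false calls numbered 28, 93, 13 and 18 in the same order. The simulated arrays held no intensity trend and were quieter than the data. The measured log2 differences from 0 Gy had SDs of 0.51, 0.99 and 0.75 at 20, 40 and 60 Gy. These figures therefore check the procedures and are not error rates for the measured arrays.

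Alternatives fixed before the data were examined were quantile normalisation, normexp background correction with an offset of 50 followed by quantile normalisation, the percentile over probes above background on all 4 arrays, centring on the E1A spike-in probes, a filter on all 4 arrays, no filter, the value table, limma without an intensity trend, and leaving out each irradiated array. The files have no mean signal column, so normexp used the median signal and the median background. Alternatives added after seeing the data kept the outlier spots, put each array on a line through the spike-in probes, removed the intensity trend against the 0 Gy array, or left the 40 Gy array out of the dose order.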

Results

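The data describe RNA from parental FaDu cells and from FaDu populations that had survived repeated X-ray exposure to totals of 20, 40 and 60 Gy. Each dose was measured on 1 array carrying 75149 non-control probes. The share of probes above background was 56.8% at 0 Gy, 57.9% at 20 Gy, 72.8% at 40 Gy and 63.3% at 60 Gy, and 40495 probes were above background on all 4 arrays. The 75th percentile of the signal was 212 at 0 Gy, 248 at 20 Gy, 442 at 40 Gy and 320.0 at 60 Gy. Repeated spots of a probe had a median SD between 0.07 and 0.09 on the log2 scale. The number of arrays limits the precision of every comparison: no dose has a replicate.

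The series asks how expression in radioresistant FaDu populations differs with the dose received. Against 0 Gy, the 20 Gy array had 2727 probes 2-fold or more higher and 1025 lower among 45034 compared. The 40 Gy array had 10241 higher and 7215 lower among 54862, and the 60 Gy array had 5481 higher and 3856 lower among 48349. Of the Agilent catalogue probes compared at 40 Gy, 13.1% were higher and 19.2% lower, while of the probes named by a plain p-number 25.1% were higher and 6.71% lower. Among probes above background on all 4 arrays, the catalogue median at 40 Gy lay −0.19 from the median over all probes and the p-number median 0.26 above it. Under quantile normalisation these values shrank to −0.05 and 0.06, with signs that also held with normexp, the spike-in line and the intensity trend removed. The catalogue split of 2211 higher and 5205 lower at 40 Gy turned to 3667 and 2209 with the percentile over probes above background on all 4 arrays, to 12229 and 53 with spike-in centring, and to 2570 and 2390 with the intensity trend removed. At 60 Gy the catalogue probes were 8.72% higher and 8.25% lower, and the p-number probes 15.4% higher and 7.88% lower. Among probes above background on all 4 arrays, the catalogue split at 60 Gy turned to 1543 higher and 1887 lower. With spike-in centring it was 7621 and 178. At 20 Gy the catalogue probes were 4.69% higher and 2.26% lower, and the p-number probes 8.21% higher and 2.5% lower. Part of these differences are lower bounds, including 4796 of the higher probes at 40 Gy, 2166 at 60 Gy and 1173 at 20 Gy.

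Across the 40495 probes above background on all 4 arrays, the SD of the log2 difference from 0 Gy was 0.51 at 20 Gy, 0.99 at 40 Gy and 0.75 at 60 Gy. Spot noise alone would place 3.94, 0.829 and 2.70 of these probes at 2-fold, against 2204, 12086 and 6379 observed. At 40 Gy bright probes were lower and dim probes higher: the median log2 difference was 0.30 in the 2nd decile of mean signal and −0.98 in the 10th. The 10th decile stood at −0.51 at 60 Gy and −0.23 at 20 Gy. The split into higher and lower depends on the filter and on the scaling. Among the probes above background on all 4 arrays it turned at 40 Gy to 5272 higher and 6814 lower, and at 60 Gy it was 3210 and 3169. With the percentile taken over probes above background on all 4 arrays, 83.8%, 83.3% and 69.9% of the counted probes were higher at 20, 40 and 60 Gy, against 72.7%, 58.7% and 58.7%. Centred on the E1A spike-in probes, the counts became 5583, 37684 and 19709, of which 95.1%, 99.7% and 97.6% were higher. That centring moved the median difference over all probes from −0.07 to 0.25 at 20 Gy, from −0.17 to 1.24 at 40 Gy and from −0.13 to 0.71 at 60 Gy. Directions of RNA classes and control genes are therefore given relative to the median over all probes where so stated. Here and elsewhere, that median is taken over the probes above background on all 4 arrays.

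**Figure D1:**
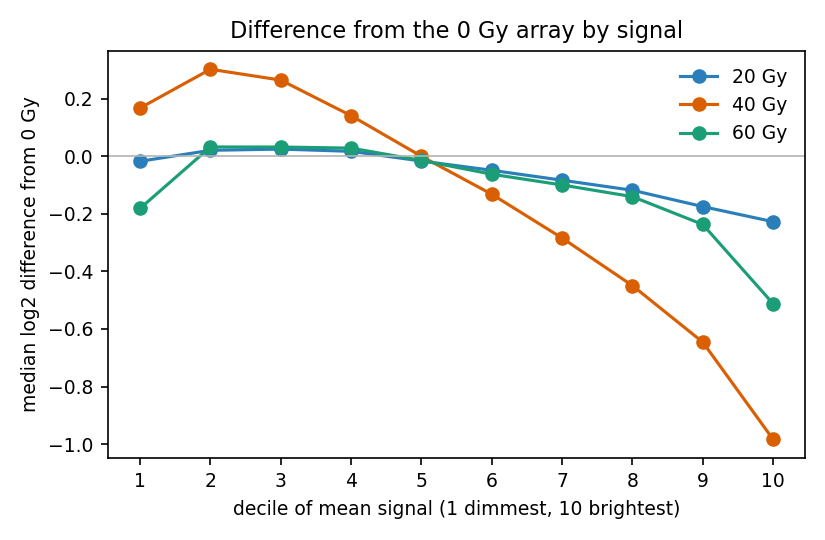
Median log2 difference from the 0 Gy array (vertical axis) in 10 equal groups of probes ordered by mean signal (horizontal axis), for the probes above background on all 4 arrays, after 75th percentile scaling. Each line is 1 array, and the 40 Gy line falls from 0.30 in the 2nd decile to −0.98 in the 10th.

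Probes of transfer RNAs, the adaptors that carry amino acids to the ribosome, reached the lowest single value of the small RNA classes, −5.86 at 40 Gy, although the RNA-number class had the lower median there (−1.56 against −1.02). Of 52 tRNA probes above background on all 4 arrays, 26 were 2-fold or more lower at 40 Gy and 25 at 60 Gy, while 0 were lower at 20 Gy. At 40 Gy 4 were higher, at 60 Gy 2, and at 20 Gy 1. The majority at 40 Gy turned with spike-in centring (17 lower and 19 higher) and with the spike-in line (16 and 17). A set of 15 was 4-fold or more lower at both 40 and 60 Gy. The median log2 difference of these 15 was 0.00 at 20 Gy with an SD of 0.17, −4.61 at 40 Gy with an SD of 0.80, and −3.83 at 60 Gy with an SD of 1.12, each SD taken over the 15 probes. These 15 were chosen for their low values, and the other 37 had a median of −0.40 at 40 Gy and −0.28 at 60 Gy. Centred on the spike-ins, the median of the 15 was −3.21 at 40 Gy and −2.99 at 60 Gy. Their median signal at 0 Gy was 13080. Among the 40443 other probes, 68 (0.168%) were 4-fold or more lower at both doses, against 28.8% of the tRNA probes. The tRNA class median lay −0.41 from that of other probes of like signal at 40 Gy (percentile 0.02 of 10000 random lists), −0.48 from it at 60 Gy (percentile 0) and 0.15 above it at 20 Gy (percentile 98.7). Under quantile normalisation these values were −0.84, −0.63 and 0.19. Relative to the median over all probes, the tRNA median was lower at 40 and 60 Gy and higher at 20 Gy under the percentile scaling, quantile normalisation, normexp, the spike-in line and removal of the intensity trend. A scaling that shifts a whole array cannot alter this value. tRNA genes come in near-identical copies, so the probes are not independent and their number is uncertain as a number of RNAs.

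Small nuclear RNA probes (snRNA, parts of the splicing machinery among others) did not share this pattern. Of 46 probes, 9 were higher and 1 lower at 40 Gy, and 4 were higher and 4 lower at 60 Gy. With spike-in centring 39 were higher and 0 lower at 40 Gy, and 15 and 0 at 60 Gy. The spike-in line gave 31 and 0 at 40 Gy, and 9 and 1 at 60 Gy. With normexp 4 of the snRNA probes were higher and 0 lower at 40 Gy, and 0 and 0 at 60 Gy. Their median lay 0.27 above that of probes of like signal at 40 Gy (percentile 95.7) and −0.07 from it at 60 Gy (percentile 30.0). Probes of small nucleolar and Cajal body RNAs, guides for chemical modification of other RNAs, numbered 241. At 40 Gy 26 of them were higher and 55 lower, with the class median −0.23 from probes of like signal (percentile 0.03). That split turned to 53 and 33 with the percentile over probes above background on all 4 arrays, 125 and 0 with spike-in centring and 95 and 4 with the spike-in line. At 20 Gy their median lay 0.21 above such probes (percentile 100), and at 60 Gy 0.09 above them (percentile 94.6). The direction at 60 Gy turns under quantile normalisation, where the median lay −0.01 from probes of like signal. The 14 probes that carry only an RNA number were −0.61 from probes of like signal at 40 Gy and −0.99 at 60 Gy (percentile 0 at both), with 11 and 10 of them 2-fold or more lower. Those counts were 3 and 6 under quantile normalisation, 3 and 7 with the intensity trend removed and 1 and 4 with the spike-in line, and the class median relative to all probes at 40 Gy moved from −1.39 to −0.39 under quantile normalisation. Against probes of like signal, that normalisation gave −0.45 at 40 Gy and −0.77 at 60 Gy. Many of the 14 probes are very bright, up to 17.0 in log2 signal at 0 Gy. The brightest of the 20 bins may hold dimmer probes, so part of the shift may be trend. In the imsncRNA group, 102 of 533 probes were higher and 49 lower at 40 Gy, with a median 0.15 above probes of like signal (percentile 99.9). That split was 152 and 11 with the percentile over probes above background on all 4 arrays, and 384 and 1 with spike-in centring. It was 305 and 4 with the spike-in line and 42 and 11 with normexp. In the RNS group of 811, the median lay −0.19 from probes of like signal at 60 Gy (percentile 0).

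**Figure D2:**
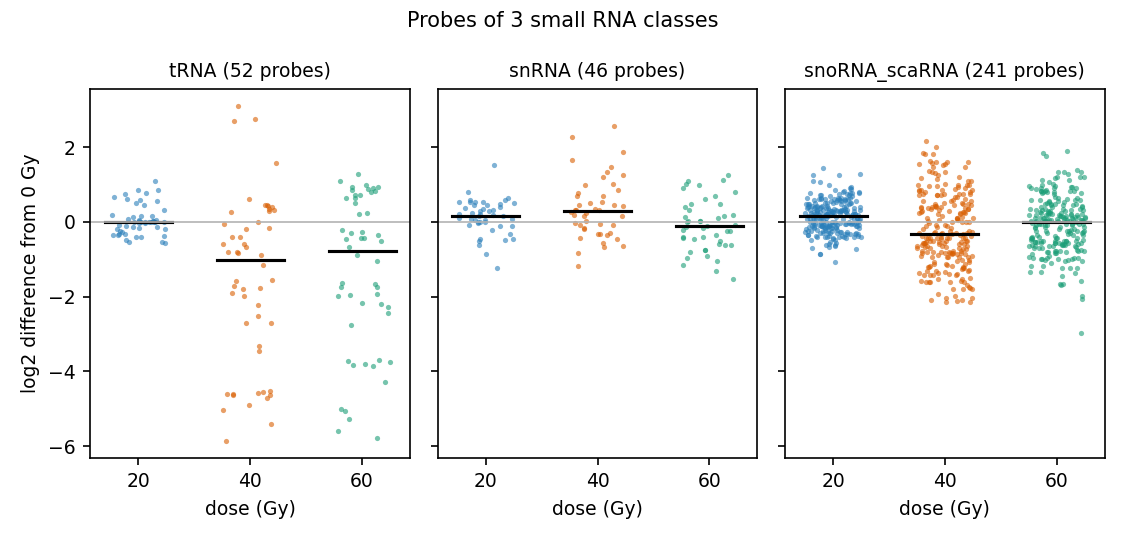
Log2 difference from the 0 Gy array (vertical axis) at 20, 40 and 60 Gy (horizontal axis) for each probe of 3 RNA classes above background on all 4 arrays, after 75th percentile scaling. Each point is 1 probe and each bar the class median. tRNA probes extend to −5.86 at 40 Gy, against −1.19 for snRNA and −2.15 for snoRNA_scaRNA probes.

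Both glycolytic control genes, GAPDH and PGK1, have probes whose names carry a 5 and a 3, read here as the 5′ and 3′ parts of the transcript. The unscaled signal of the PGK1 5′ probe was 673 ± 38.5 (SD over 10 spots of 1 array) at 0 Gy, 1240 ± 89.5 at 20 Gy, 964 ± 67.5 at 40 Gy and 1257 ± 73.9 at 60 Gy. The PGK1 3′ probe read 7804 ± 210.0, 8807 ± 316, 7182 ± 192 and 7807 ± 316 in the same order. The 5′ change exceeded the 3′ change of PGK1 by 0.71 ± 0.05 (log2, standard error from spots) at 20 Gy, 0.64 ± 0.05 at 40 Gy and 0.90 ± 0.04 at 60 Gy. GAPDH went the other way at 60 Gy, where its 5′ change lay −0.58 ± 0.05 from its 3′ change. At 20 and 40 Gy that value was 0.08 ± 0.05 and −0.17 ± 0.05. Relative to the median over all probes, PGK1 5′ was 0.72 higher at 20 Gy and 0.44 higher at 60 Gy on the log2 scale, and −0.38 from it at 40 Gy, with these directions kept under the 4 kinds of scaling compared. GAPDH 3′ lay −1.07 from that median at 40 Gy and −0.55 at 60 Gy. With the intensity trend removed it lay −0.07 from it at 40 Gy, and at 60 Gy the direction turned to 0.04. With the spike-in line the direction turned at both doses, to 0.06 at 40 Gy and 0.07 at 60 Gy.

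**Figure D3:**
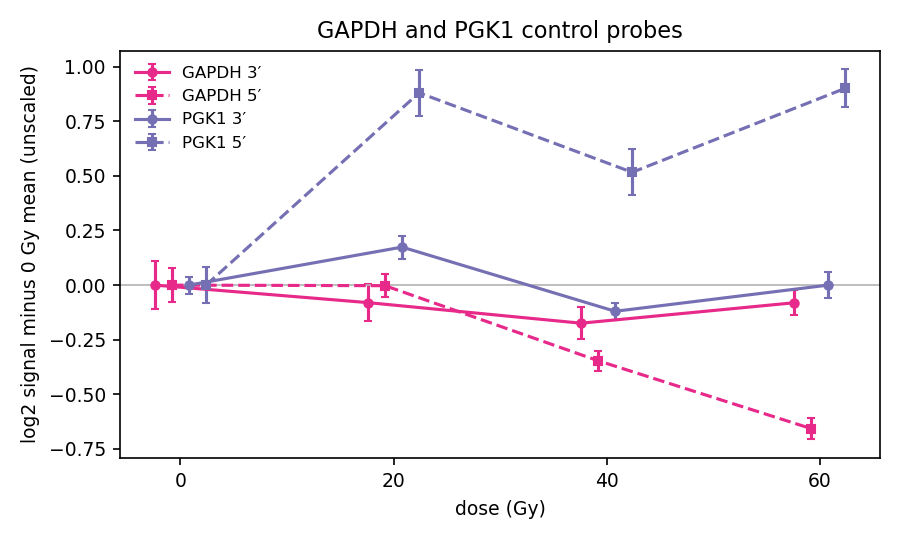
Log2 signal of the GAPDH and PGK1 control probes minus their mean at 0 Gy, unscaled (vertical axis), by dose (horizontal axis). Points are means over 8 to 10 spots of 1 array and bars are the SD over those spots. PGK1 5′ lies 0.88 above its 0 Gy value at 20 Gy and 0.90 above it at 60 Gy, while GAPDH 5′ lies at −0.66 at 60 Gy.

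Probes that differed from 0 Gy in 1 direction at all 3 doses were mostly higher. There were 1395 higher and 263 lower at 2-fold or more, among 44430 compared. The probe p18324 was 6.44-fold, 10.8-fold and 15.3-fold higher at 20, 40 and 60 Gy, with log2 differences of 2.69 ± 0.03, 3.44 ± 0.04 and 3.93 ± 0.07 (standard errors from 3 spots per array). The Agilent probe A_23_P218442 was 10.99-fold, 6.68-fold and 6.50-fold higher, with larger spot errors of 0.38 at each dose over 2 spots. The probe p7227 was 5.45-fold lower at 20 Gy, 18.0-fold lower at 40 Gy and 5.42-fold lower at 60 Gy, and p15331 was 5.12-fold, 13.6-fold and 16.1-fold lower. Each kept its direction at 2-fold or more in all 11 settings, with sizes that moved: on the log2 scale at 40 Gy, A_23_P218442 ranged from 1.49 to 4.15, p18324 from 3.42 to 5.26, p7227 from −4.19 to −2.76 and p15331 from −4.15 to −2.35. These probes were picked for large differences in the same data, and the settings that change only the filter cannot alter a fold. At 20 and 60 Gy the values nearest 0 were 2.08 and 1.49 for A_23_P218442 and −1.70 and −2.45 for p15331, all with normexp. For p7227 at 60 Gy it was −1.60, with spike-in centring. A further view of the same contrast counts probes above background on the 3 irradiated arrays and not at 0 Gy, of which there were 1891. The p-number probes made up 924 of these and the Agilent catalogue probes 618. At 0 Gy, 12465 of all 30464 p-number probes were above background, and 24336 of all 34235 catalogue probes. More p-number than catalogue probes were therefore available to appear. Only 102 probes were above background at 0 Gy and on none of the irradiated arrays. The 0 Gy array had the smallest share of probes above background, 56.8%, against 57.9%, 72.8% and 63.3% at 20, 40 and 60 Gy. Detection alone therefore favours probes gained over probes lost. Quantile normalisation gave 71.1% higher in place of 84.1% for the count over all 3 doses, and centring on the spike-ins gave 99.5%.

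The 3 differences share the 0 Gy array, so their overlap was set against simulated arrays without effects. Over the 40495 probes above background throughout, 924 were 2-fold or more in the same direction at all 3 doses. Simulated arrays gave 0 such probes with spot noise and 1139 when the whole spread between the arrays was taken as noise. Independent lists would share 15.8 higher and 8.90 lower probes, against 749 and 175 observed. The covariance of the 40 and 60 Gy differences was 0.522, against 0.0152 with spot noise and 0.280 with all spread as noise. The corresponding correlation across probes, which are not independent replicates, was 0.703 against 0.624 and 0.502. For 20 and 40 Gy it was 0.653, over both simulated values, of which the higher was 0.609. For 20 and 60 Gy it was 0.480, under both simulated values of 0.573 and 0.499. For 20 and 40 Gy the covariance was 0.329 against 0.0152 and 0.279, and for 20 and 60 Gy it was 0.184 against 0.0152 and 0.278. The control could not be split. The 924 probes lie between both simulated values, so part or all of the overlap at 3 doses may come from the shared array. The same count with another array set against the rest was 4417 for 40 Gy, 1151 for 60 Gy and 250 for 20 Gy, against 1658 for 0 Gy. At 40 Gy 3844 of those 4417 probes were higher on the 40 Gy array than on every other.

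For an order by dose, 1536 probes increased and 1394 decreased at each step from 0 through 20 and 40 to 60 Gy with a total of 2-fold or more. The majority turned to decreases with the filter on all 4 arrays (789 and 1134), without a filter (1690 and 1843) and under quantile normalisation (1423 and 1508). Of the 12 possible orders of the 4 arrays this one ranked 5, and 3 under quantile normalisation. The order with the most probes was 0, 20, 60, 40 Gy, with 9178. Without the 40 Gy array, 8937 probes were ordered over 0, 20 and 60 Gy. Centring on the spike-ins left 2982 probes in dose order, 96.7% of them increasing against 52.4%.

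Between consecutive doses, 7751 probes were higher and 4141 lower at 40 than at 20 Gy, and 3311 were higher and 7633 lower at 60 than at 40 Gy. From 20 to 40 Gy the majority turned with the filter on all 4 arrays (3468 higher and 3844 lower) and without a filter (11739 and 12530). From 40 to 60 Gy that filter gave 2687 higher and 3064 lower. From 20 to 40 Gy, 43 of 82 tRNA probes compared were lower and 11 higher, and 68 of 272 snoRNA_scaRNA probes were lower and 18 higher. From 40 to 60 Gy, 28 of 86 snRNA probes were lower and 5 higher, and 180 of 783 imsncRNA probes were lower and 15 higher. The p-number probes made up 3900 of the probes higher from 20 to 40 Gy and 3700 of those lower from 40 to 60 Gy. Between 20 and 60 Gy, 3768 probes were higher and 3536 lower at 60 Gy. Under quantile normalisation 54.7% of the counted probes were higher from 20 to 40 Gy, against 65.2%, and 48.2% from 40 to 60 Gy, against 30.3%. With the percentile over probes above background on all arrays these shares were 85.4% and 12.9%, and with spike-in centring 99.6% and 3.56%.

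Comparing the 3 irradiated arrays with the parental array, limma called 527 probes higher and 42 lower among 55181 at an adjusted p under 0.05. The higher calls comprised 263 p-number, 159 Agilent catalogue, 69 versioned p-number, 27 imsncRNA, 4 snRNA, 4 RNS and 1 rRNA probes. The lower calls comprised 17 Agilent catalogue, 15 tRNA, 7 p-number, 2 versioned p-number and 1 imsncRNA probes. The median effect was 2.73 on the log2 scale for the higher calls and −2.78 for the lower. The fit takes each signal as measured, also where a probe is not above background, so the size for the higher calls is uncertain. Of the 569 calls, 535 were 2-fold or more in their direction at all 3 doses. The 15 tRNA calls are among the other 34, as 0 tRNA probes were 2-fold lower at 20 Gy. Of the 527 higher calls, 295 were not above background at 0 Gy. p18324 had a limma adjusted p of 0.000228, p15331 of 0.000739, A_23_P218442 of 0.00114 and p7227 of 0.00124. The calls numbered 0 under quantile normalisation, under the filter on all 4 arrays and without the 40 Gy array. Of the 569 calls, 232 higher and 38 lower were above background on all 4 arrays, and these lost the call under that filter with the fold unchanged. The fit drew on 69.5 prior degrees of freedom from other probes against 2 of its own. For a straight line in dose, limma called 0 probes, with 5989 at an unadjusted p under 0.05. It called 12003 without the 60 Gy array, 284 without the 20 Gy array, 1234 with spike-in centring, 73 with the percentile over probes above background on all 4 arrays and 10 without a filter. The fits without an array have 1 residual degree of freedom.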

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

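The tests in this part were chosen after the results were seen, except that the counts under the percentile scaling and quantile normalisation were fixed beforehand. The bounds for the tRNA and PGK1 tests were widened later, because the first ones took near-identical probes as independent or rested on spot error alone. Classes were picked out where the class median lay outside the middle 95% of random lists of like signal in opposite directions at different doses, under both the percentile scaling and quantile normalisation. None of these differences between doses was tested, since each dose has 1 array. The tRNA median lay 0.15 above other probes of like signal at 20 Gy, −0.41 from them at 40 Gy and −0.48 at 60 Gy. The snoRNA_scaRNA median lay 0.21 above such probes at 20 Gy and −0.23 from them at 40 Gy. The Agilent catalogue median lay −0.016 from such probes at 20 Gy, −0.23 from them at 40 Gy and 0.036 above them at 60 Gy. The imsncRNA median lay −0.051 from such probes at 20 Gy and 0.15 above them at 40 Gy. The catalogue class holds 23473 of the 40495 probes. Medians of random lists that large vary little, so very small shifts are picked out, as at 20 and 60 Gy.

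The low tRNA values at 40 and 60 Gy were weighed against 2 technical explanations. The class medians could exclude neither, and the counts of probes do not decide the question. A weaker response of bright probes predicts the median of probes of like signal. The tRNA median lay −0.41 from it at 40 Gy and −0.48 at 60 Gy. Probes were resampled in 6 sets by the last number of their names, which is not shown to group near-identical probes. The 95% bootstrap intervals were −3.95 to 0.54 and −3.43 to 0.81. With the intensity trend removed, 24 of 52 tRNA probes were still 2-fold or more lower at 40 Gy and 24 at 60 Gy, with 11 and 12 higher. Of 23473 Agilent catalogue probes, 2390 and 1321 were lower there, with 2570 and 1760 higher. A response that depends on signal alone does not predict this excess of lower tRNA probes. The catalogue probes were not matched on signal, however, and near-identical tRNA probes are not independent. These counts therefore do not decide the question. A loss of small RNAs of every class before labelling predicts snRNA values as low as the tRNA values. Each taken against probes of like signal, the snRNA median lay 0.69 above the tRNA median at 40 Gy (interval over sets −0.39 to 4.23) and 0.41 above it at 60 Gy (−0.99 to 3.42). With 6 sets of tRNA probes the intervals hold 0, so the class medians exclude neither explanation. Other classes went both ways against probes of like signal at 40 Gy: snoRNA_scaRNA −0.23, RNA-number −0.61, rRNA −0.40 (7 probes) and imsncRNA 0.15. At 60 Gy they stood at 0.09, −0.99, −0.37 and −0.07. These classes were not part of the test. Of 46 snRNA probes, 1 was 2-fold or more lower at 40 Gy and 4 at 60 Gy, with 9 and 4 higher. Of 52 tRNA probes, 26 and 25 were lower, with 4 and 2 higher. A loss as large in every class does not predict counts this unlike, but the counts are not matched on signal. Probes of like signal had a median of −0.61 for tRNA and 0.005 for snRNA at 40 Gy, and −0.30 and −0.05 at 60 Gy. Part of the contrast may therefore be trend, and the counts do not decide the question. A loss that acts only on RNAs as short as tRNAs, and a lower tRNA content of the cells, were not tested. The last is a hypothesis that may be followed up with replicate cultures.

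The 40 Gy array lay farther from 0 Gy than the 60 Gy array did, with 17456 probes at 2-fold against 9337. With the intensity trend removed the counts were 12517 and 8584, and with quantile normalisation 13627 and 7897. The excess at 40 Gy therefore shrank without ending, to under 1.5 times the 60 Gy count in the first case and over it in the second, so how much of it the trend accounts for remains open. The trend itself may be a compressed response of the whole array. The slope of the differences on mean log2 signal was −0.18 over 8 E1A spike-in probes (95% interval −0.39 to 0.03) and −0.16 over the array's own probes. The interval holds both 0 and the slope of the probes, so a compressed array and a real change cannot be told apart with 8 spike-in probes. A change in the cells at 40 Gy was not tested, as dose and array coincide.

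The PGK1 5′ probe was higher against its 3′ probe on every irradiated array. If labelling starts at the 3′ end, which was not examined here, RNA degradation would lower the 5′ probes of both control genes. At 60 Gy PGK1 stood at 0.90 ± 0.04 and GAPDH at −0.58 ± 0.05 (standard errors from spots). The intensity trend at each probe's signal left 0.61 of the 0.71 at 20 Gy, 0.11 of the 0.64 at 40 Gy and 0.59 of the 0.90 at 60 Gy. Spot error does not measure the spread between arrays. With the trend removed, the middle 95% of differences between 2 random probes ran from −1.41 to 1.42 at 20 Gy and from −2.06 to 2.07 at 60 Gy, and all these values lie inside. Random pairs join different genes, so this range does not measure the spread between 2 probes of 1 transcript and cannot decide the question. On that condition of labelling from the 3′ end, PGK1 went against the direction that degradation predicts on all 3 irradiated arrays. GAPDH went with it at 40 and 60 Gy. Degradation and the trend therefore stay open for these single arrays. Control probes named for mouse and rat PGK1 5′ moved like the human one. They read 398, 696, 582 and 689, and 509, 908, 756 and 947, at 0, 20, 40 and 60 Gy. The rat GAPDH 5′ probe fell from 13075 (1 spot) at 0 Gy to 4265 at 60 Gy, and the dim mouse one from 40.6 to 31.3. Which RNA these probes read is not known. A change in PGK1 transcript forms, or another RNA read by the 5′ probe, is a candidate explanation that these arrays do not test.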

How the results depend on the processing

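No paired analysis was possible because each dose has 1 array, so a replicate number pairs nothing. The median over several probes of a gene, the gene lists and the count over long non-coding RNAs were not run for lack of gene names, and slide and scan time were not run as blocks because all 4 arrays share them. The cause of the changes below was not tested unless stated. The alternatives on outlier spots, the spike-in line, the intensity trend and the dose order without 40 Gy were added after seeing the data.

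Counts are given for 20, 40 and 60 Gy against 0 Gy, all 3 doses, dose order, 40 against 20 Gy and 60 against 40 Gy, where they moved over 1.5 times from 3752, 17456, 9337, 1658, 2930, 11892 and 10944. With normexp they were 468, 5509, 2316, 137, 795, 3191 and 2698. With spike-in centring, which shifts all probes of an array alike, 5 moved beyond that factor: 37684 and 19709 at 40 and 60 Gy, 4046 at all doses, 32305 and 20107 for the steps. The spike-in line gave 27471, 15007, 2844, 23036 and 16802 for the same 5. The filter on all 4 arrays, which tests fewer probes, gave 2204 at 20 Gy, 924 at all doses, 1923 in dose order, 7312 and 5751 for the steps. Without a filter they were 7324, 27450, 14555, 3216 at all doses and 24269 for 40 against 20 Gy. Leaving out an irradiated array gave 1824 to 6088 probes in the same direction at the remaining doses, the highest without 20 Gy, with 2776 without 60 Gy. Leaving 40 Gy out of the dose order gave 8937, as fewer steps must go 1 way. Quantile normalisation, the value table, the outlier spots and removal of the trend kept all 7 counts within 1.5 times.

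The 569 limma calls against the parental array became 0 with quantile normalisation (3149 at an unadjusted p under 0.05), normexp (2369), the filter on all 4 arrays (2793), the trend removed (3339) and eBayes without an intensity trend (3244). They became 879 with the percentile over probes above background on all 4 arrays and 95 with spike-in centring, 73 of these among the 569. Leaving out an irradiated array gave 0 to 1819: 0 without 40 Gy (2751 unadjusted), 586 without 60 Gy and 1819 without 20 Gy. The dose trend, 0 by limma with 5989 unadjusted, became 73 with that percentile, 1234 with spike-in centring and 10 without a filter. Leaving out an irradiated array gave 0 to 12003, with 284 without 20 Gy and 12003 without 60 Gy, each on 1 residual degree of freedom.

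The tRNA probes 2-fold or more lower at 40 Gy numbered 17 with spike-in centring and 16 with the spike-in line against 26, fewer than the 19 and 17 higher there (against 4), and 20 to 25 at 60 Gy throughout. The snoRNA_scaRNA median at 60 Gy relative to all probes turned from 0.14 to −0.0090 with quantile normalisation and −0.041 with the spike-in line. Signal over background limits dim probes, since 19666 probes were above background on no array.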

Other observations

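Probes above background on the 3 irradiated arrays and not on the parental one numbered 1891. They included 261 p-number probes with a version number, 40 imsncRNA, 25 RNS, 10 snoRNA_scaRNA, 9 snRNA and 4 tRNA probes. The 102 probes read at 0 Gy alone included 46 Agilent catalogue and 45 p-number probes. A 2-fold bound was reached by 1295 of the 1891 and 82 of the 102. The 0 Gy array had the smallest share of probes above background (56.8%), which favours the larger count. The 40 and 60 Gy arrays shared 2173 of their higher probes and 1954 of their lower ones among those above background throughout, against 418 and 533 for independent lists. Both differences share the 0 Gy array, and simulated arrays without effects gave 0.100 of each with spot noise and 1059 and 1058 with the whole spread between arrays taken as noise.

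The E1A spike-in probes, RNAs added to the sample, lay on average −0.09 from their 0 Gy level at 20 Gy, −0.34 at 40 Gy and −0.25 at 60 Gy on the unscaled log2 scale. The 8 probes differed in direction, from −1.09 to 1.60 at 40 Gy. The 75th percentile of the array's own probes lay 0.23, 1.06 and 0.60 above its 0 Gy value.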
